A study of Danio rerio with 2 samples.

How the data were processed

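The study compared zebrafish larvae carrying the hu2081 and hu2117 alleles of vhl, the von Hippel-Lindau tumour suppressor gene, with their siblings at 7 days after fertilisation. Per the labels' protocols, mutants and siblings were separated by morphology, and total RNA of each genotype was isolated from 40 larvae taken in equal parts from 4 clutches. Genotype here means mutant or sibling. Because sorting was by morphology, the sibling pool may hold larvae of more than 1 vhl genotype, including carriers. RNA of the 2 genotypes was labelled with the dyes Cy3 and Cy5 and hybridised together to 2 Agilent arrays of 60-base probes. On array 1 the mutant RNA carried Cy5 and the sibling RNA Cy3, and on array 2 the dyes were swapped. The labels describe 1 pool per genotype and do not mention separate RNA extracts, so the 2 arrays were treated as 1 replicate, a technical dye swap. The SD given with a mean is therefore the spread between 2 hybridisations and holds no variation between clutches or animals. For this reason differences were described by size on each array, and no p-value is given as a result. Both file headers name the same slide, so slide could not be set as a block.

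The spot intensity values were read from the scanner files as deposited. Per the file headers, these came from Agilent Feature Extraction 10.2.1.3, and the mean signal and local background columns had been neither subtracted nor normalised. The same files hold processed signals, an intensity that the software had background-subtracted, detrended and dye-normalised, per the file headers. They also hold the deposited log10 ratio of red over green made from those processed signals. Other deposited columns are flags of 0 or 1 for each spot and channel that mark outliers, saturation and signal well above background, per the file headers. The submitters' processing notes name Agilent Feature Extraction and limma without versions. The authors' deposited table lists probes with a signed fold change, read here as a score, with a minus sign for a negative fold. It also gives a p-value for each probe, and the deposited table states neither the direction of its comparison nor whether the p-value was adjusted.

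Intensities were processed in R 4.3.3 with limma 3.58.1 and the data.table package (version 1.17.8). The background median was corrected with normexp at an offset of 50, and red over green ratios were normalised by loess within each array with control spots at weight 0. Outlier-flagged spots were left out, which removed 25 spots on array 1 and 13 on array 2. Repeated spots of a probe were averaged. The ratio of array 2 was turned so that each log2 value is mutant over sibling. A gene was represented by its brightest probe over both arrays, and it was measured if at least 1 channel was well above background on each array. Tables and plots were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

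Of 43603 probes, 16072 were named through a RefSeq accession in a gene table of assembly GRCz12tu, 1053 through a current symbol and 1452 through an older symbol, and 25026 kept the name in the file. This gave 36099 names, of which 5971 had more than 1 probe. For 128 probes named by accession, the name in the file now belongs to another gene. A matching error that gave 1 of these probes to a proteasome list was corrected after list values had been seen, and the lists fixed beforehand did not change. Probe positions are those in the files, whose header names the build danRer2 (Zv4) while 2845 probes lie on scaffolds named Zv7. The build of the printed positions is therefore not settled.

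Each array held 43803 non-control spots and 1417 control spots. On array 1, 80.9% of spots were well above background in green and 93.9% in red, and on array 2 these shares were 87.1% and 94.6%. The median green signal was 358 on array 1 and 397 on array 2, against a background of 67.5 and 67. The median red signal was 679 and 682, against a background of 151 and 149. No spot was saturated (0 on each array). For 50 probes printed 5 times, the median SD of the log2 ratio was 0.049 on array 1 and 0.046 on array 2. The number of arrays limits the precision.

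A gene was counted as higher or lower if its log2 ratio was at least 1, or at most -1, on each array. The median of each of 28 gene lists was set against 10000 random lists of the same size, matched on brightness in 20 bins, and the range that holds 95% of them is given. This range describes these arrays and is no test across animals. The lists were HIF (hypoxia-inducible factor) targets, glycolysis, gluconeogenesis, endothelium, erythroid, haematopoietic progenitor, neutrophil and macrophage, lymphoid and thymus, acute phase and complement, iron handling, liver, exocrine pancreas, endocrine pancreas, intestine, kidney, skeletal muscle, heart, photoreceptor, lens, brain, cartilage and bone matrix, epidermis, cell cycle, oxidative phosphorylation, fatty acid oxidation, lipid synthesis, stress and apoptosis, and a ribosomal and reference list. Some genes stand in 2 lists. The lists, the thresholds and the rule for named genes were fixed before the data were examined. The rule took vhl, the 10 genes with the highest and the 10 with the lowest mean ratio that had a gene symbol in the file, up to 4 members of each pathway list and up to 2 of each tissue or reference list with the largest absolute ratio. Genes outside this rule are said to have been chosen after their values were seen. Lists of the proteasome core, proteasome partners, the immunoproteasome, pigment cells, the dioxin response, the glucocorticoid response, sulfide oxidation and myelin were written after the gene table had been looked at (for the partners, before their single values had been seen), and appear in the closing part.

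The procedure was tested on simulated data for this comparison, with 33533 genes of which 200 were changed. Every simulated gene had the same noise, set from the median difference between the arrays, without variation between pools. No unchanged gene passed 2-fold on both arrays (0 genes). That noise made such a pass very unlikely, so the 0 does not cover real genes with a larger spread between arrays. Of 50 genes simulated at 2-fold, 17 passed the threshold, and all 50 simulated at 3-fold and all 50 at 4-fold passed. Of 28 lists not changed as a group, 2 lay outside the 95% range, though single members could be among the changed genes. Alternatives were other background corrections, median centring in place of loess, Aquantile scaling, other filters on dim probes, the removal of saturated probes, the mean over a gene's probes, each array alone, other size thresholds, and limma over the 2 arrays with a Benjamini-Hochberg adjusted p-value threshold of 0.05.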

Results

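Gene expression of zebrafish larvae transheterozygous for the vhl alleles hu2081 and hu2117 was measured against that of their siblings at 7 days after fertilisation. The product of vhl takes part in the degradation of hypoxia-inducible factor (HIF), a transcription factor that acts when oxygen is low. RNA pooled from 40 mutants and from 40 siblings, sorted by morphology, was hybridised to 2 two-colour arrays in opposite dye orientation, and 33524 genes were measured. Values are log2 ratios of mutant over sibling, as the mean of the 2 arrays ± the SD between them. This SD is technical, because there was 1 pool per genotype and hence no biological replicate.

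The vhl transcript was higher in mutants, with a log2 ratio of 0.71 ± 0.22 and array values of 0.55 and 0.87. It was measured by a single 60-base probe, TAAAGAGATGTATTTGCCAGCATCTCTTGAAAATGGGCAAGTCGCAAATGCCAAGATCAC, placed in the file on chromosome 6 from 27316732 to 27316791. The file's header and scaffold names give different genome builds, so the build of these positions is not settled. The place of the probe relative to the mutations is not given in the sources used here, and its value does not check the labels.

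Genes of red blood cells and of the HIF response stood among those highest in mutants, such as alas2 and egln3, and digestive enzymes of the pancreas, such as cel.1 and amy2a, among those lowest. In all, 296 genes were at least 2-fold higher and 70 at least 2-fold lower on both arrays, and 0 passed that size in opposite directions. With the scanner's processed signals 14 genes did so, and with median centring 1. The lower count was 40 with median centring in place of loess and 112 on array 1 alone. Genes higher in mutants thus made up 80.9% of those past 2-fold. At 4-fold the counts were 56 higher and 4 lower. Across genes the log2 ratios of the 2 arrays correlated with r = -0.76 as hybridised and 0.76 once the dye swap was turned, where genes are not independent replicates. The turned r was 0.34 with median centring and 0.48 from the scanner's own log ratios. The median SD between arrays was 0.085 over all genes and 0.095 among those past 2-fold.

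**Figure D1:**
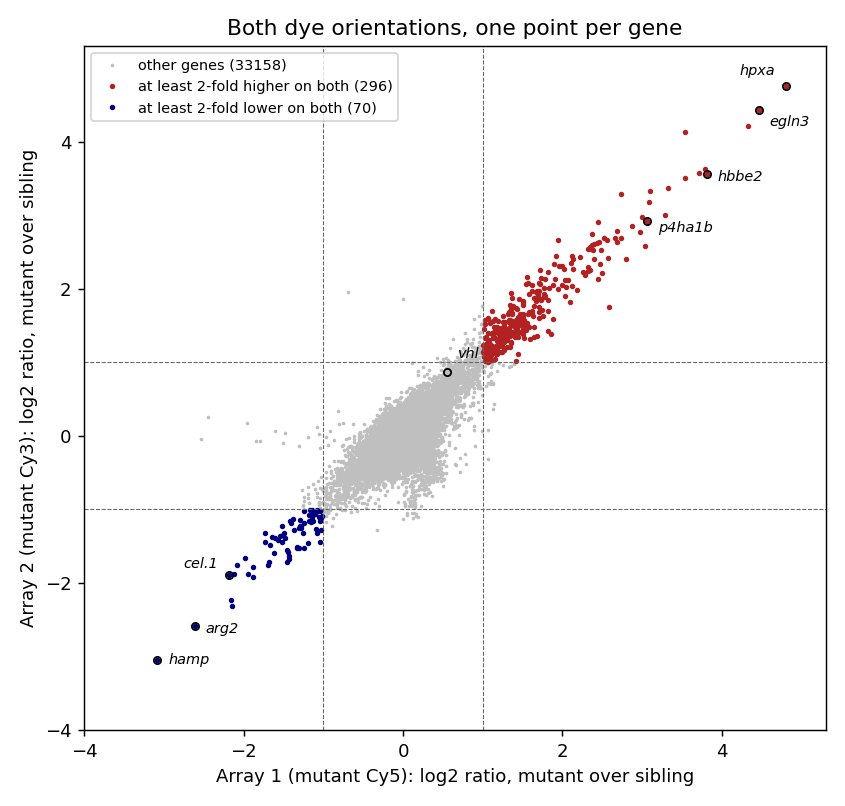
Log2 ratio of mutant over sibling for each gene on array 1 (x axis, mutant labelled with Cy5) and on array 2 (y axis, mutant labelled with Cy3), with dashed lines at 2-fold. The 296 genes past 2-fold on both arrays in the upper right include hpxa and egln3, and the 70 in the lower left include hamp and arg2.

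By the brightest probe, the gene with the highest ratio among those with a symbol in the file was hpxa, which encodes hemopexin, a plasma protein that binds haem, at 4.78 ± 0.04 or 27.5-fold. The other 3 hpxa probes gave 4.65, 4.09 and 3.38, and the mean over its probes, 4.23, lay below egln3. By the brightest probe egln3 came next, a prolyl hydroxylase that acts on HIF and is itself a HIF target, at 4.45 ± 0.03 or 21.8-fold. The egln3 probe is placed on chromosome 17 from 13106156 to 13106215, and the hpxa probe on chromosome 9 from 26809806 to 26809865, with the same doubt about the build. The other 8 of the 10 highest were hbbe2, slc4a1a, alas2, epb41b, hbae3, p4ha1b, hbae1.1 and mb, from 3.69 for hbbe2 to 2.86 for mb, the gene of the oxygen-binding muscle protein myoglobin, for which a second probe gave 2.35. At the other end stood hamp, the gene of the iron-regulating hormone hepcidin, at -3.06 ± 0.03, which is 8.36-fold lower. The arginase gene arg2 followed at -2.60 ± 0.02. The other 8 of the 10 lowest were cel.1, cpa1, amy2a, cpb1, txnl1 at -1.84, ela2l, the astacin-type protease gene c6ast3 at -1.50 and the proteasome ATPase gene psmc1b at -1.50. Besides hamp and arg2, the 4 genes at least 4-fold lower were tat, encoding tyrosine aminotransferase, at -2.19 and zgc:92590 at -2.23, both named after their values were seen.

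The HIF target list, fixed before the data were examined, was higher in mutants. Its median log2 ratio was 0.60 over 53 measured members, above the 95% range of random lists of equal brightness, -0.05 to 0.05. Of these members 21 were at least 2-fold higher and 0 lower, and 32 passed neither size. On both arrays 38 were positive and 6 negative. Chosen after their values were seen, the erythropoietin gene epoa stood at 0.16, ca9 at 0.05 and igfbp1b at -0.99. After egln3 the largest ratios were those of angptl4, a secreted inhibitor of lipoprotein lipase, at 3.13 ± 0.06, and of the collagen-modifying hydroxylases p4ha1b at 2.99 ± 0.10 and plod1a at 2.99 ± 0.01. The member mxi1, chosen after its values were seen, had values of opposite sign on the 2 arrays, -2.44 and 0.26. The list median was 0.41 with no background subtraction and 0.42 with the mean over all probes of a gene.

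Glycolytic enzymes were also higher as a group, with a median of 0.63 over 31 members, of which 11 were at least 2-fold higher and 0 lower. The lactate dehydrogenase gene ldha stood at 2.67 ± 0.02 and the phosphoglycerate mutase gene pgam1a was 5.26-fold higher. The enolase gene eno1a, at 2.16 ± 0.59, differed more between arrays. The member whose mean was the list median, the phosphofructokinase gene pfkmb, chosen after its values were seen, had opposite signs on the 2 arrays, -0.70 and 1.95. For the glyceraldehyde-3-phosphate dehydrogenase gene gapdhs, at 2.08 ± 0.14, another probe gave 0.04. Gluconeogenesis, with only 5 members measured, had a median of 0.18, inside its random range, and 0 members past 2-fold. Its median was 0.050 on array 1 alone. Its named members were pck2 at 0.90, fbp1a at -0.30, pcxa at 0.20, with a second probe at -0.13, and fbp2 at 0.18.

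Red blood cell genes gave the highest list median, 0.996 over 38 members, with 19 at least 2-fold higher and 0 lower. They included the embryonic globin gene hbbe2 at 3.69 ± 0.17, slc4a1a, which encodes the anion exchanger of the red cell membrane, at 3.52 ± 0.03, alas2, the first enzyme of haem synthesis in red cells, at 3.35 ± 0.03, and the membrane skeleton gene epb41b at 3.21 ± 0.16. Other globin genes among the 10 highest with a symbol in the file were hbae3 at 3.14 ± 0.20 and hbae1.1 at 2.87 ± 0.14. The globin gene hbae4, outside that ranking and chosen after its values were seen, was at 3.01 ± 0.39. Embryonic globin genes include close copies, so which of these a probe read is uncertain. The globin genes hbaa2 at 0.11, hbba2 at 0.06 and hbbe3 at 0.58, chosen after their values were seen, were short of 2-fold. The lowest of 3 slc4a1a probes gave 0.99. The haematopoietic progenitor list had a median of 0.07 over 13 members, inside its random range and 0.033 on array 2 alone, with 0 past 2-fold. There mycb stood at -0.89, and the blood regulators tal1 at 0.75 and lmo2 at 0.73. The gene fli1 stood at 0.68, with probes from -0.02 to 0.86.

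**Figure D2:**
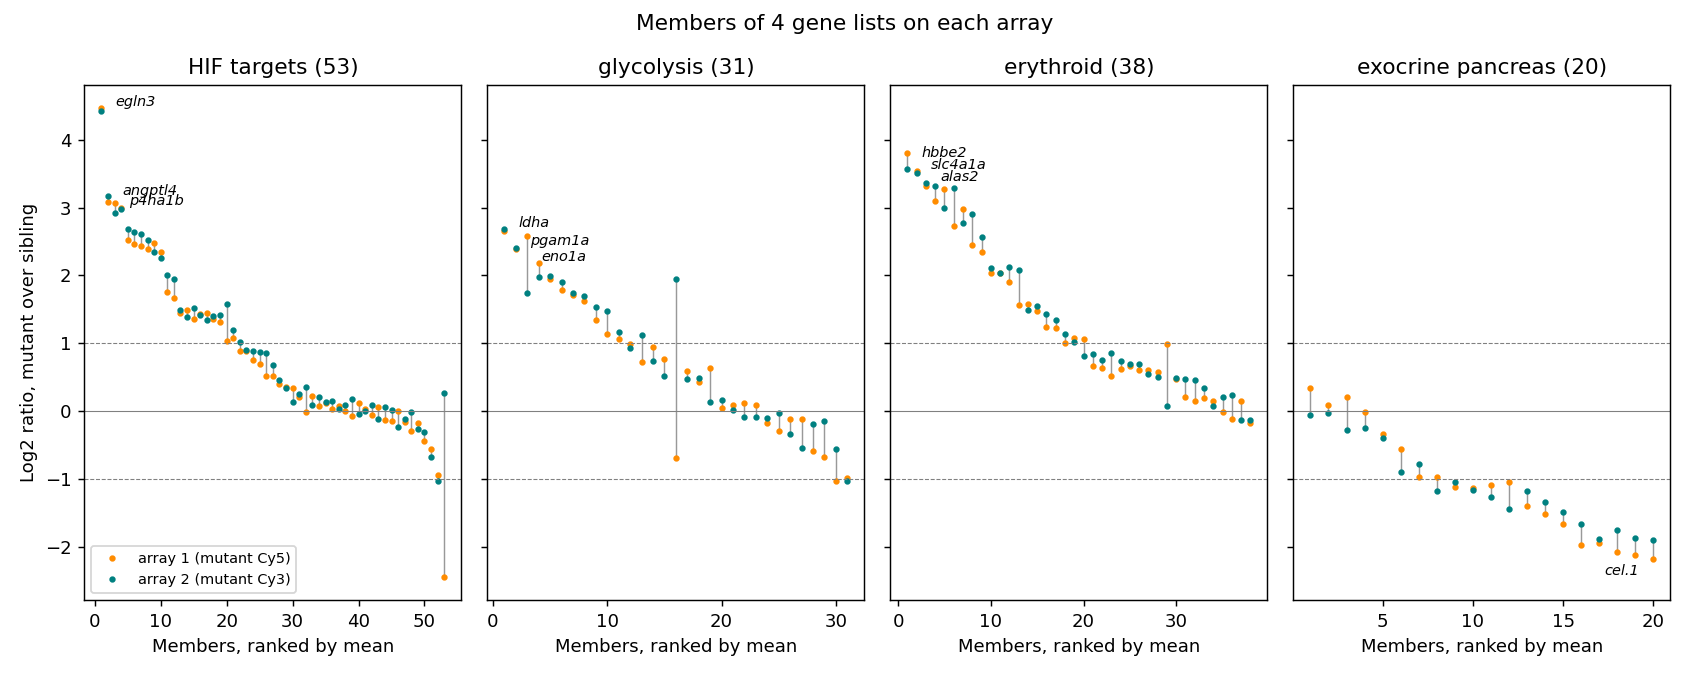
Log2 ratio of mutant over sibling (y axis) for each measured member of 4 gene lists, ranked by mean (x axis), with orange points for array 1, teal points for array 2 and dashed lines at 2-fold. Of the members, 21 HIF targets, 11 glycolysis genes and 19 erythroid genes lay at least 2-fold higher on both arrays, and 12 exocrine pancreas genes at least 2-fold lower.

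Digestive enzymes of the exocrine pancreas were lower, with a median of -1.16 over 20 members, of which 12 were at least 2-fold lower and 0 higher. The lipase gene cel.1 stood at -2.04 ± 0.21 and the carboxypeptidase gene cpa1 was 3.99-fold lower, with an SD of 0.18 on the log2 scale. Among the 10 lowest genes were also the amylase gene amy2a at -1.92 ± 0.23, the carboxypeptidase gene cpb1 at -1.91 ± 0.05 and the elastase gene ela2l at -1.82 ± 0.22. These enzyme families hold close paralogs, so the assignment to single genes is uncertain. Endocrine pancreas genes had a median of -0.04 over 10 members, inside the random range and of either sign under other settings, with the somatostatin genes sst2 at 0.31 and sst1.1 at -0.20. That difference between lists was not tested.

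Plasma protein and iron genes went both ways. The acute phase and complement list had a median of 0.48 over 18 members, with 4 higher and 1 lower. Its higher members included the complement gene c3a.2 at 2.28 ± 0.06, the prothrombin gene f2 at 1.49 ± 0.23, for which a second probe gave 0.70, and the ceruloplasmin gene cp, which was 2.63-fold higher. The iron list, with 18 members, had a median of 0.20, with 2 higher and 3 lower. Besides hpxa and hamp it held tfa, the gene of the plasma iron carrier transferrin, at 2.80 ± 0.32 and the ferritin-like gene fthl31 at -1.28 ± 0.05, one of a family of close copies. The iron median turned to -0.075 when probes had to be above background in both channels. The liver list, to which hpxa and tfa also belong, had a median of 0.21 over 24 members, with 5 higher and 0 lower.

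Endothelial genes had a median of 0.28 over 32 members, with 2 higher and 0 lower. These were the tight junction gene cldn5b at 2.02 ± 0.05 and plvapb at 1.07 ± 0.02, while clec14a stood at 0.85 and kdr, a receptor of vascular endothelial growth factor, at 0.76 with a further probe at 0.11. Cell cycle genes had a median of 0.58 over 42 members, with 7 higher and 0 lower. The largest ratios by the brightest probe were those of the mitotic kinase gene cdk1 at 1.82 ± 0.08, for which a second probe gave 1.01, rrm2l at 1.76 ± 0.25, stmn1a at 1.51 ± 0.05 and the topoisomerase gene top2a at 1.38 ± 0.26. Oxidative phosphorylation had a median of 0.00 over 59 members, inside its random range and of either sign under other settings, yet 3 members were at least 2-fold higher. These were the cytochrome oxidase subunit genes cox6b1 at 2.49 ± 0.11 and cox5b2 at 1.62 ± 0.28, and ndufa4l2a at 1.75 ± 0.11, while the pyruvate dehydrogenase gene pdha1a stood at -0.46. Fatty acid oxidation had a median of 0.28 over 25 members, with 2 higher and 0 lower. Of these, cpt1b, which serves fatty acid entry into mitochondria, stood at 1.12 ± 0.05 and the thiolase gene acaa2 at 1.03 ± 0.03, whereas acads at 0.87 and hadhab at 0.74, with another probe at 0.18, were short of 2-fold. Lipid synthesis had a median of 0.06 over 29 members, just inside its range, whose upper end was 0.07, and of 0.14 on array 2 alone and 0.11 with median centring. It had 0 members at least 2-fold higher and 1 lower, the phosphatidate phosphatase gene lpin1a at -1.33 ± 0.06. Its members mid1ip1l at 1.04, hmgcra at 0.85 and insig1 at 0.79 were not past 2-fold on both arrays. The stress and apoptosis list had a median of 0.01 over 35 members, inside its random range and of either sign under other settings. With 0 past 2-fold, its members ran from ddit3 at -0.95 and hsp90aa1.1 at -0.90 to sesn3 at 0.90 and hsp90b1 at 0.94.

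Lists of other tissues were set beside these because the RNA came from whole larvae. Above their random ranges lay cartilage and bone matrix at a median of 0.49 (28 members, 7 higher), photoreceptors at 0.42 (37 members, 4 higher), skeletal muscle at 0.41 (24 members, 4 higher) and heart at 0.23 (14 members, 1 higher), each with 0 lower. Their leading members were the collagen genes col1a1a at 2.15 ± 0.22 and col1a1b at 2.13 ± 0.25, the cone opsin genes opn1mw2 at 2.45 ± 0.12 and opn1lw1 at 1.63 ± 0.01, the muscle genes mb and acta1b, the latter at 1.96 ± 0.12, and the heart genes nppa at 1.65 ± 0.22 and cmlc1 at 0.87 ± 0.05. Collagens, opsins and actins have close copies, and a second opn1mw2 probe gave 1.27. Below their ranges lay intestine at -0.28 (26 members), lens at -0.28 (28 members) and kidney at -0.15 (20 members), with 0 genes at least 2-fold lower in each. The kidney median was -0.087 on array 1 alone and -0.11 on array 2 alone, and the intestine median -0.18 on array 2 alone. In the intestine list apoa4a stood at 1.66 ± 0.23, the single member at least 2-fold higher, and apoea at 0.83. Lens crystallin gene crygmx was at -0.86 and the lens gene grifin at -0.83. In the kidney list slc20a1a was at -0.79 and atp1a1a.4 at -0.53.

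Inside their ranges lay brain at -0.04 (26 members), neutrophils and macrophages at 0.03 (23 members), lymphoid and thymus genes at 0.04 (8 members) and epidermis at 0.03 (21 members). The epidermis median was 0.12 on array 1 alone, 0.14 on array 2 alone and 0.17 with median centring, each above the upper limit of 0.092 found for the mean of both arrays. The brain median ranged from -0.091 to -0.035 over the settings, that of neutrophils and macrophages from -0.0053 to 0.061 and that of lymphoid and thymus genes from 0.012 to 0.073. Among brain genes the myelin gene mbpa was at -1.03 ± 0.01, the single member at least 2-fold lower, and plp1b at -0.89. Skin keratin genes krt5 and krt17, which have close copies, stood at 1.74 ± 0.20 and 1.11 ± 0.20. The myeloid regulator cebpa was at -0.54, with a second probe at -0.15, and lgals9l1 at -0.33, while the recombinase genes rag2 and rag1 were at 0.31 and -0.12. In total 14 of the 28 lists lay above their random range and 4 below.

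The ribosomal and reference list, whose genes serve all cells, had a median of 0.14 over 74 members with 0 past 2-fold. It was led by hprt1 at 0.47 and actb1 at 0.46. It too lay above its random range, -0.10 to 0.06. Lying above the range was thus not particular to pathway or tissue lists. The reference median was 0.24 on array 1 and 0.02 on array 2, and 0.36 with median centring in place of loess. With median centring, the medians of iron handling at 0.19, liver at 0.21, heart at 0.23, fatty acid oxidation at 0.29 and endothelium at 0.29 lay below that of the reference list.

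**Figure D3:**
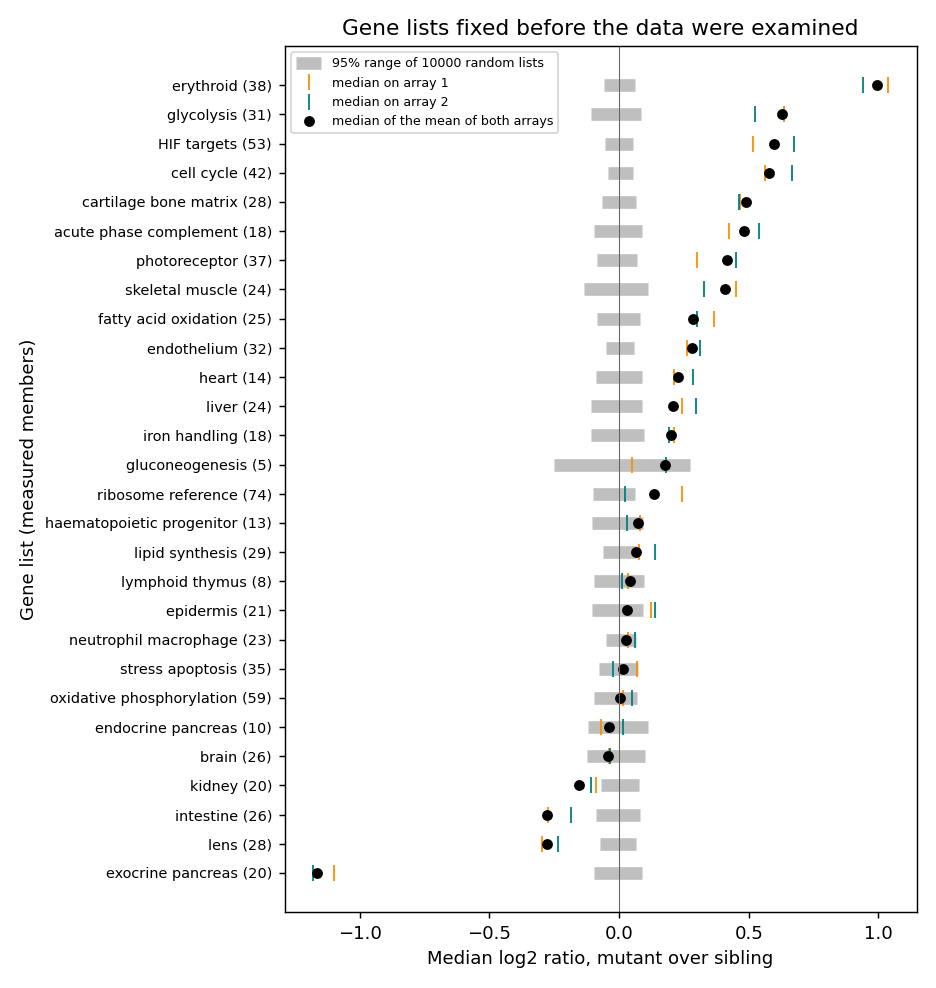
Median log2 ratio of mutant over sibling (x axis) for each of 28 gene lists (y axis), with a black dot for the mean of both arrays, orange and teal ticks for arrays 1 and 2, and a grey bar for the range that holds 95% of random lists matched on size and brightness. The erythroid list lies highest at 0.996 and the exocrine pancreas list lowest at -1.16.

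The authors' deposited table held 2247 rows for 2231 probes, 1460 with a positive and 787 with a negative fold change, the smallest absolute fold being 1.4. It does not state its direction. All of its 2246 rows that had a ratio here carried the same sign as mutant over sibling, and log2 fold changes correlated across them with r = 0.9999. Both sets of values come from the same 2 arrays, and the table's rows were selected by size. The agreement thus bears on direction and processing and is no independent evidence. The authors' deposited table gave egln3 a fold change of 21.6, hpxa 27.3, hamp -8.22 and vhl 1.615. Of the probes computed here as at least 2-fold different on both arrays, all 395 higher and all 96 lower stood in the authors' deposited table with that sign.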

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

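The threshold that singled out this result, a signal 1.2 times that of spots without a target, was set after the values had been seen. Control probes for the E1A spike-in transcripts, which no comparison used, had a median red signal of 308.1 on array 1, against 208.1 at the dark corner spots. On array 2 the red signal was 314.2 against 207.8. In green, the signal was 218.9 against 183.7 on array 1 and 228.8 against 188.8 on array 2. The 10 probes, with 320 spots on each array, had red over green log2 ratios from -0.32 to 0.21 on array 1 and from -0.15 to 0.33 on array 2. The protocols in the labels do not mention spike-in RNA, and no explanation was tested.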

How the results depend on the processing

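All alternatives given here were chosen before the data were examined, except those of the proteasome list. With the scanner's processed signals vhl was at 0.96. The HIF target median was 0.41 without background subtraction and 0.42 with the mean over probes. With median centring the number of lower genes was 40, of which 38 were among the 70, and the agreement between arrays was r = 0.34. From the scanner's own log ratios r was 0.48. At 1.5-fold 725 genes were higher and 288 lower, and at 4-fold 56 and 4. With each array alone, lower genes numbered 96 to 112 (112 without array 2) and higher genes 322 to 391, and the larger counts follow from dropping the demand on the other array. For the other values the cause was not tested. With probes above background in both channels the iron median was -0.075, over fewer genes, and with loess replaced by median centring the reference list was at 0.36. Limma over the 2 arrays, applied to genes whose mean over both was at least 2-fold, gave 348 higher and 86 lower. That looser size rule alone gave 348 and 87. The p-values of limma measure only the spread between 2 hybridisations. At the 2-fold threshold the share of higher genes under other background corrections, normalisations, filters, probe rules and single arrays lay between 74.2% (array 1 alone) and 87.3% (median centring). Under the 5 settings that can move a named gene by more than the SD between arrays, 316 of 440 values stayed within it and 124 moved further. Single arrays cannot exceed that SD by construction, and filters leave a gene's probe as it is. The single sign change of a named gene under any setting was that of pcxa, at -0.015 on array 1 alone. Of 252 list medians under 9 settings, 179 stayed, 72 moved and 1, the iron median, changed sign although it had been outside its random range. The neutrophil and macrophage, endocrine pancreas, oxidative phosphorylation and stress medians, all inside their random ranges, took either sign depending on the setting. The proteasome median lay between -0.84 and -0.73. Aquantile leaves ratios as they are and the saturation filter removed 0 probes, so neither tests anything and neither is counted. Slide as a block was not run because both arrays lie on the same slide. Each ratio already sets mutant against sibling on the same array. With 1 pool per genotype, no pairing by clutch or animal was possible. Signal over background limited green most, with 80.9% of spots above it on array 1.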

Other observations

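The gene lists described here were written after the gene table had been looked at. The single values of the proteasome partners had not been seen when that list was written. For the other lists, the place against a random range therefore only describes them and is no support. Of the tests below, those on dilution, dye bias, less liver RNA and the second hamp probe were chosen after the result was seen.

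Subunits of the proteasome, the complex that degrades ubiquitin-tagged proteins, were lower in mutants. All 32 measured members of the core list had negative ratios on both arrays, from -1.50 for psmc1b to -0.25 for psma2a, with a median of -0.79 against a random range of -0.13 to 0.10. Of them 4 were at least 2-fold lower on both arrays, psmc1b, psmb7 at -1.21, psmb4 at -1.16 and psmd3 at -1.06. Partners of the proteasome had a median of -0.29 over 24 members, of which 5 were positive and 16 negative on both arrays, the negative ones including vcp, at -1.27 on array 1 and -0.73 on array 2, and nsfl1c, at a mean of -0.96. The immunoproteasome list, with 9 members, had a median of 0.06, inside its random range, with 0.05 on array 1 and -0.03 on array 2.

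Pigment cell genes had a median of 0.24 over 11 members, above their random range. There tyrp1b at 1.55 and pmelb at 1.26 were at least 2-fold higher, with pmela at 1.03 and dct at 0.94, while tyr stood at -0.07 and mitfa at -0.06. Among dioxin response genes, with a median of 0.14 over 9 members, above their random range, cyp1c1 was at 1.35 and cyp1b1 at 1.16, and cyp1a at 0.14. The ribosomal and reference list, also at a median of 0.14, lay above its range too. The sulfide oxidation list had a median of -0.21 over 6 members, just below its random range, whose lower end was -0.19. Its median was -0.36 on array 1 and -0.07 on array 2. In this list the mitochondrial enzyme genes sqor and ethe1 were at 2.71 and 1.18, and the genes of hydrogen sulfide synthesis cth and cbsb at -0.83 and -0.60. Glucocorticoid response genes had a median of -0.16 over 10 members, inside the random range, with tat at -2.19 and fkbp5 at -0.88. Myelin genes had a median of -0.11 over 10 members, also inside. On array 1 alone both medians, -0.21 and -0.20, lay below the lower ends of these ranges, -0.18 and -0.13. On array 2 alone they were -0.10 and -0.098.

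Lower ratios of acinar pancreas enzymes, at a median of -1.16, may reflect less acinar RNA per larva. Normalisation set the bulk of genes near 0, so these medians cannot show how much all tissues were diluted together. Dilution by more red cell RNA would still move acinar and other tissue lists alike. The lowest median of the 13 other tissue lists was -0.28, that of lens, beside intestine at -0.28, kidney at -0.15 and skeletal muscle at 0.41. Such a shared dilution thus would not set the acinar list apart. With median centring the list median shrank to -1.02 and the higher of the 2 array medians from -1.10 to -0.69, so loess may account for part of the size but not for the whole. The reference list also rose with median centring, from 0.14 to 0.36, so this upward move was not particular to the acinar list. Dye bias would give the arrays opposite signs, and the higher of their medians was -1.10. A smaller dilution, feeding, size and developmental delay of the mutants stay open and were not tested.

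Hepcidin, at -3.06, was lower while the liver list was not. Less liver RNA in the mutant pool would lower that list too, but the lower of its 2 array medians was 0.24. A misreading probe is argued against by the other hamp probe, which had a mean of -2.88. A lower transcript level of hamp within liver cells is a hypothesis that was itself not tested. The pattern was found and these other explanations were weighed on the same 2 arrays. The single pool per genotype leaves variation between larvae unmeasured.

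The lower proteasome subunits may share control with their partner genes. The median of the partners was -0.29, as such control would need, although no partner was among the genes past 2-fold that had been seen beforehand. The partner list also held the proteasome subunit gene sem1, at -0.36, so it was not wholly separate from the subunits. An effect of loess on bright spots is argued against as the whole cause by the proteasome median of -0.74 with median centring, and dye bias by the higher of the 2 array medians, -0.73. No transcription factor was tested, and a difference in stage between the pools stays open. Such a difference could lower subunits and partners alike, so the partner median does not tell it from shared control.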
